A study of Homo sapiens with 4 samples.

How the data were processed

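H3K4me2 chromatin immunoprecipitation libraries of A375 cells were analysed from the processed files, 2 libraries of A375 negative and 2 of A375 positive cells. Groups were taken from the cell type label of each library. The titles of both A375 positive libraries carry the same line token, whereas the name of 1 of their deposited lists carries a different one, so the labels do not settle how these replicates relate. Their lists differ (Jaccard index 0.865) and they were counted as 2 libraries. The series design calls the libraries of a line biological replicates, and nothing says how separate their cultures were. Only the limma p-values take in the spread between these libraries. The other p-values treat regions, genes or windows as units and describe these lists. The replicate numbers are names given here and pair no samples. Per the submitters' processing notes, the tools were BWA, SAMtools, deepTools and MACS2 and the genome build was hg19. Their versions, settings and thresholds are not given in the sources used here.

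The authors deposited a peak list per library, called with MACS per the file names, that holds coordinates and no score, fold, p-value or read count. Median peak widths were between 3340 and 3365 bp, no list had a peak under 1499 bp, and the widest peak in any list measured 19923 bp. No filter that would set such limits is stated. The deposited lists per line were the union of the 2 libraries' lists: after merging, 55670 intervals for A375 positive and 51404 for A375 negative were identical to the deposited ones. The authors' deposited table of merged peaks counts 48120 regions shared by the lines, 7327 in A375 positive and 2940 in A375 negative. Another deposited table gives, for 140232 regions, the nearest transcription start, its distance and a HOMER annotation class. Its regions are not those of the peak lists (2 were identical to a library peak). A merged list that also draws on another histone mark was not used, nor were 2 of its columns, which belong to other samples.

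The 4 lists were merged with bedtools 2.31.1 at an overlap of at least 1 bp into 58387 regions, in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. A region counts as specific to a line when both of its libraries and neither library of the other line have a peak in it. Each region took the gene, class and distance of the annotated region with the largest overlap, 1 region had none, and 1.07% overlapped annotated regions of 2 or more genes. For shares and tests of the promoter class, a region counted when any annotated region it overlapped was a promoter. The gene is the nearest start in the authors' annotation and need not be the regulated gene. Host genes of introns were found by matching the annotation's RefSeq transcripts to symbols (GRCh38.p14 RefSeq table, names only). Coordinates are 1-based on hg19.

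Covered bases were compared by the Jaccard index. Promoter classes and chromosomes were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 3 and 46 tests. The 24 gene lists were fixed before the data were examined and tested per direction against 10000 random lists matched on the number of regions per gene, with adjustment over 48 tests. The members of 1 of these lists are not reported here. Covered length per gene was summed in kb per library, and log2(kb + 0.5) was centred on each library's median and fitted with limma 3.58.1 in R 4.3.3 for genes with a peak in at least 2 libraries. Log2 changes are on that scale. They are not given for genes at 0 kb in a line, where they depend on the value added. Values in kb are as summed, before centring. A threshold of 0.05 on the adjusted p was used throughout. Intervals are exact binomial intervals at 95% and cover counting error only.

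Both statistics were tested on simulated data. Of 160 lists of 40 genes given a 4-fold rate of specific regions among 18458 genes, 97.5% were called, and 1.62% of 800 null lists had an unadjusted p under 0.05. This simulation used the rate of positive-specific regions and drew regions independently. It does not show the power for the rarer negative-specific regions, for shorter lists or for regions that cluster. The peak length fit on 18043 simulated genes called 35.8% of genes changed by 0.5 on the log2 scale, 62.7% at 1 and 84.8% at 2, with 5 false calls among 127.

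Genes were named by a rule fixed before the data were examined. Per direction these are the 12 genes whose specific region ranks highest in its own lists by the lower of the replicates' percentiles. To these come the 8 with the most specific regions and none in the other direction, and up to 4 members of each gene list with the most specific regions. The last are the 5 with the largest change in peak length among genes past the threshold. MITF, SOX10, AXL and EGFR are named whatever their values. The ranking was planned on peak scores. As the lists hold none, peak width took their place, a choice made after the files were seen. List members called in the peak length fit are also named, and those outside the rule were chosen after their values were seen, as were windows and runs of neighbouring regions.

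A test of read counts per region had been planned, and was not run because the deposited values are not counts. Alternatives planned before the data were examined were a shared call at 50% of the peak length, a gap of 1 kb, each library left out in turn, autosomes alone, the deposited lists per line, other definitions and backgrounds for promoters, other matchings of gene lists, and other added values (0.1 and 2 kb), filters and no centring for peak length. Those resting on peak scores were replaced, after the data were seen, by the peaks at or above the median width of each list and by lists cut to 48131 peaks by width. Matching on distance and a pooled odds ratio over distance classes were added then too.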

Results

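Dimethylation of histone H3 at lysine 4 (H3K4me2), a mark found at promoters and enhancers that are active or primed, was mapped by chromatin immunoprecipitation and sequencing in A375, an established human skin melanoma cell line. The submitters compared 2 lines of A375 cells, which they name A375 negative and A375 positive, with 2 libraries described as biological replicates for each. Both lines had passed 5 rounds of sorting for aggressiveness according to the labels, which do not say what property makes a line positive or negative. The measurement in each library was the list of its H3K4me2 peaks on hg19. The A375 negative libraries held 48131 and 49978 peaks, and the A375 positive libraries 51496 and 54238, a mean of 49054.5 ± 1306 (SD, n = 2) against 52867 ± 1939 (SD, n = 2). Together the peaks of a library covered 185.4 and 191.3 Mb in A375 negative and 197.0 and 207.4 Mb in A375 positive. The lists carry no height, fold or read count, so the sequencing depth is unknown, and a region without a peak had no call in that library rather than a measured absence of the mark.

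The H3K4me2 landscapes of the lines were largely shared. Of 58387 regions obtained by merging the 4 lists, 43247 (74.1%) had a peak in every library. The Jaccard index of covered bases was 0.872 between the A375 negative replicates and 0.865 between the A375 positive replicates, and it lay between 0.794 and 0.808 for the 4 pairs taken across the lines. About 50% of the peaks of each library fell in introns and between 37.8% and 38.9% between genes.

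Beyond this shared set, 3710 regions (6.35%) carried a peak in both A375 positive libraries and in neither A375 negative library, and 1329 regions (2.28%) showed the opposite pattern, a ratio of 2.79. These are called positive-specific and negative-specific regions. The other 2 ways of dividing the 4 libraries into pairs gave 799 and 337 such regions in all, against 5039 for the division by line. With 3 divisions the smallest attainable p of an exact test is 0.33, so this contrast is descriptive. The 799 divided unevenly, with 681 in the pair of the longer list of each line and 118 in the pair of the shorter lists. Uneven counts thus also arose where the lines were mixed. Cutting the lists to equal length by dropping the narrowest peaks left 2394 positive-specific and 2162 negative-specific regions, although equal length itself draws these counts together.

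**Figure D1:**
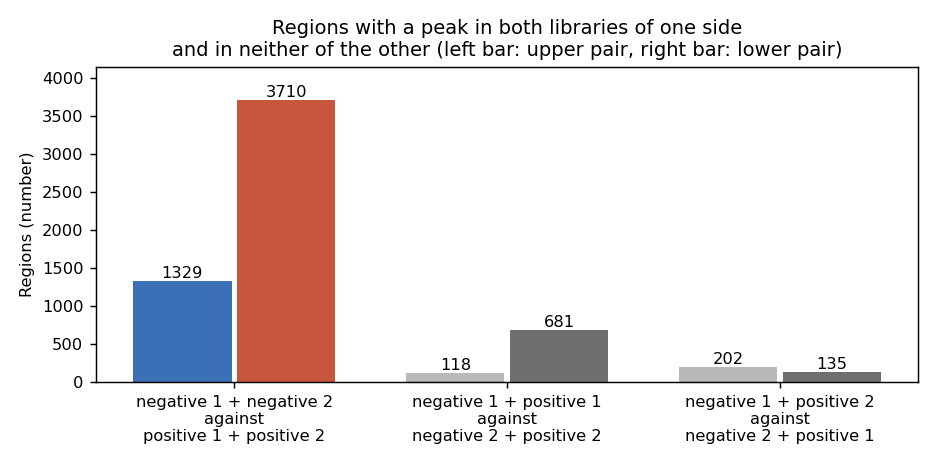
Number of regions with a peak in both libraries of a pair and in neither library of the other pair, for the division by line (coloured bars) and the other 2 divisions (grey bars). The bars for the lines reach 1329 and 3710 regions, and no bar of the other divisions exceeds 681.

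Among genes without a negative-specific region, positive-specific regions were most numerous at PCDH7, a protocadherin gene nearest to 15 of them. It was followed by LRP1B, a low-density lipoprotein receptor-related gene, with 14, and GABRA2, a GABA-A receptor subunit, and ELTD1, an adhesion G protein-coupled receptor now named ADGRL4, with 12 each. INTU followed with 11, PLA2G4A and MIR4735 with 10 each and MKRN9P with 9, a count that SEMA6D also reached. Some of these regions lay far from the start they are named after. At PCDH7, 13 of the 15 were intergenic, and the farthest lay 2649 kb away. All 11 at INTU were intergenic, 277.5 to 972.4 kb away, and the farthest at PLA2G4A lay 1718 kb away. At GABRA2 the regions ran from position 46263055 to 46648989 of chromosome 4, with 10 between genes, 1 in an intron of the gene and 1 at its promoter. No peak was assigned to GABRA2 in either A375 negative library, against 43.7 ± 1.80 kb of peaks in A375 positive (SD, n = 2). At ELTD1 they ran from 79295932 to 79820207 of chromosome 1, with 11 between genes and 1 in an intron, and the peak length was again listed at 0 in A375 negative and reached 39.4 ± 0.798 kb in A375 positive (SD, n = 2). Of the 14 regions at LRP1B, 12 lay in its introns, and its peak length rose from 13.0 ± 0.901 to 54.1 ± 2.25 kb (SD, n = 2; limma adjusted p = 0.00795).

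**Figure D2:**
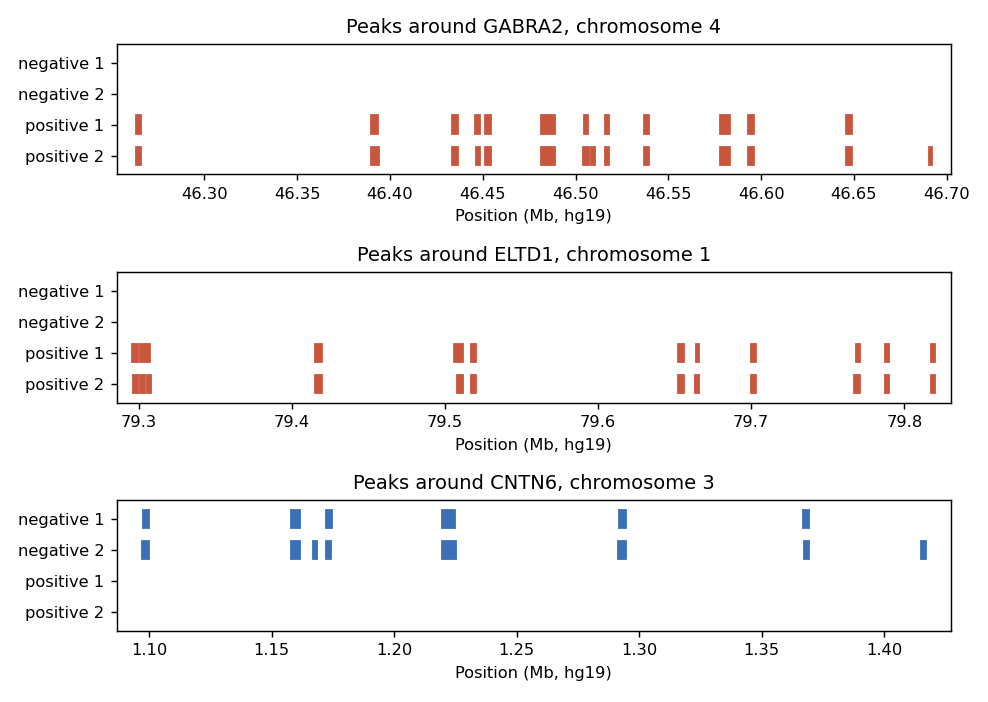
H3K4me2 peaks of each library (rows) drawn to scale along hg19 in Mb around GABRA2 and ELTD1, whose regions were positive-specific, and CNTN6, whose regions were negative-specific. The A375 negative rows are empty at GABRA2 and ELTD1, where the A375 positive libraries held 12 and 14 peaks and 12 and 12 peaks, and the A375 positive rows are empty at CNTN6, where the A375 negative libraries held 6 and 8.

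Other genes without a peak in A375 negative were LPHN2, a latrophilin receptor, with 16.3 ± 0.853 kb of peaks in A375 positive, all 4 of its specific regions intronic, LOC340017 with 14.6 ± 1.82 kb, and LUZP2 with 14.5 ± 0.516 kb and a specific region at its promoter (SD, n = 2 for each). The widest positive-specific region was 9086 bp long and lay at 86654729 to 86663814 of chromosome 4, in intron 3 of ARHGAP24 (nearest start MIR4451). The next by width of peak were intergenic regions of 7670 bp near GABRA2 (chromosome 4, 46481180 to 46488849) and of 7095 bp near DCAF4L2 (chromosome 8, 88740397 to 88747491), followed by 6830 bp in intron 1 of SLC8A1, the sodium-calcium exchanger (chromosome 2, 40554407 to 40561236). The rest of the 12 ranked highest by peak width lay nearest to PCDH18, MYADML, NRXN3, GJA1, PTPRD, ABRA, MIR6715B and LUZP2, and were 5273 to 6399 bp long.

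Among genes without a positive-specific region, negative-specific regions were most numerous at MAF and CDH7, each nearest to 8. The transcription factor gene MAF had 77.2 ± 8.49 kb of peaks in A375 negative and 46.5 ± 1.70 kb in A375 positive (SD, n = 2; limma adjusted p = 0.0209). Of its 8 negative-specific regions, 7 were intronic and none lay in an intron of MAF. The widest lay in intron 7 of the neighbouring gene WWOX (chromosome 16, 79039925 to 79043768). The cadherin gene CDH7 had 27.3 ± 1.62 against 4.13 ± 0.607 kb (limma adjusted p = 0.00795), with a negative-specific region at its promoter. MIR548AX and LINC00494 followed with 7 regions each. The 7 regions named after MIR548AX were all intronic, the widest in intron 2 of LDB2, a LIM domain-binding gene, whose own 4 negative-specific regions accompanied a peak length of 37.9 ± 2.38 against 12.4 ± 1.42 kb (limma adjusted p = 0.015). CNTN6, a contactin of neuronal adhesion, had 6 regions, 5 of them in its introns, NTRK3-AS1 also had 6, and LINC01205 and the nuclear receptor gene ESRRG had 5 each.

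Peaks assigned to CNTN6 covered 22.99 ± 5.42 kb in A375 negative and were listed at 0 in A375 positive. The same held for AJAP1 (8.78 ± 0.326 kb), C14orf64 (8.15 ± 1.37 kb), MOXD2P (6.15 ± 2.48 kb) and the ion channel gene ASIC2 (5.72 ± 0.344 kb), each with n = 2. The widest negative-specific region measured 7617 bp and was intergenic, 30.3 kb from POM121L4P (chromosome 22, 21009646 to 21017262). Ranked by the narrower of the replicates' peaks within their lists, it was followed by 6255 bp near LINC00377 (chromosome 13, 81909945 to 81916199), 6021 bp near LDB2 (chromosome 4, 17028133 to 17034153) and 6058 bp in intron 2 of CNTN6 (chromosome 3, 1219293 to 1225350). A further region of 5191 bp lay in intron 1 of the collagen gene COL6A3, 1.93 kb from a start. COL6A3 also had 2 positive-specific regions, and its peak length of 25.3 ± 1.51 kb in A375 negative and 30.1 ± 2.48 kb in A375 positive did not pass (limma adjusted p = 0.290). The others of the 12 ranked highest by peak width lay nearest to DCDC5, FAM129B, REG1A, IKZF2, ZFP64, MIR4427 and C14orf64, and were 4147 to 5454 bp long.

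Across all genes with peaks, summed peak length was higher in A375 positive at 1018 genes and lower at 477 of 18048 tested (limma, adjusted p under 0.05), and 3866 genes had an unadjusted p under 0.05. With lists of equal length these counts were 793 and 729. Leaving out an A375 negative library gave 194 or 290 higher and 42 or 59 lower, and leaving out either A375 positive library gave 0 calls in each direction, with 3416 and 3306 genes at an unadjusted p under 0.05. Every call on peak length given here therefore rests on both A375 positive libraries.

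Among genes of melanoma cell states, the calls on peak length fell on a few loci of each list. Of the 26 melanocyte lineage genes tested, KIT, the receptor for stem cell factor, rose from 30.2 ± 1.28 to 50.1 ± 6.11 kb (SD, n = 2; log2 change 0.66, SE 0.08, limma adjusted p = 0.0282), SLC45A2, a melanosomal transporter, fell from 1.89 ± 0.547 kb to 0, and 24 did not pass. The fall at SLC45A2 rests on 1 region, whose peak in negative replicate 2 measured 1499 bp, the shortest width in any list. KIT also had 3 positive-specific regions. MITF, the lineage's regulator, had 2 positive-specific regions, the wider at 69760669 to 69763124 of chromosome 3, among 28 regions in all, and 90.4 ± 1.92 against 99.5 ± 5.87 kb (limma adjusted p = 0.316). SOX10 lay in a region found in all 4 libraries (chromosome 22, 38374738 to 38385528, over intron 2 of the gene), with 9.95 ± 0.156 against 10.5 ± 0.268 kb. In the 33 genes of the undifferentiated or invasive state, CTGF, SLIT2 and the lymphatic growth factor gene VEGFC rose, VEGFC from 20.0 ± 0.264 to 32.2 ± 3.68 kb, and TCF4 fell from 50.4 ± 0.237 to 39.97 ± 3.46 kb. Without centring, the limma adjusted p was 0.0532 for KIT and 0.120 for TCF4, in a range over the alternatives of 0.0278 to 0.0931 and 0.0151 to 0.121. AXL, a receptor tyrosine kinase of that state, had 10.0 ± 0.104 against 9.84 ± 0.0764 kb (limma adjusted p = 0.386), and EGFR 16.6 ± 1.57 against 15.8 ± 0.396 kb (limma adjusted p = 0.373), neither with a specific region. In the 20 neural crest-like genes, AQP1, CDH19, SEMA3C and TFAP2B rose and none fell, and SEMA3C had 6 positive-specific regions. AQP1 had no peak in A375 negative and only 2.66 ± 0.106 kb in A375 positive (SD, n = 2). Counts adjusted over the list alone were the same for these 3 lists.

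Axon guidance and neuronal adhesion, the list with the most genes tested, held the most calls in number. Of 42 genes tested, 8 rose in A375 positive (EPHA3, EPHA5, NRXN3, SEMA3A, SEMA3C, SEMA3D, SEMA6D and SLIT2), 2 fell (EPHA4 and NCAM2) and 32 did not pass. Adjusted over the list alone, 9 rose, with DCC added, and 2 fell. By share, the fibroblast markers had more, with 3 of 11 called. Over all genes, 1018 of 18048 rose and 477 fell, and no list's calls on peak length were tested against matched genes. The semaphorin genes SEMA6D, with 9 positive-specific regions, and SEMA3D, with 5, went from 47.2 ± 0.997 to 76.3 ± 4.52 kb and from 51.3 ± 2.40 to 85.0 ± 1.66 kb. The ephrin receptor gene EPHA4, with 4 negative-specific regions and 1 positive-specific region, went from 59.1 ± 2.66 to 39.2 ± 1.96 kb (log2 change -0.65, SE 0.06, limma adjusted p = 0.0189). The negative-specific region of EPHA4 ranked highest by peak width was intergenic, 792.1 kb from the start. The highest positive-specific region of SEMA6D was intronic, 32.55 kb from the start. ROBO2, a receptor for SLIT proteins, had 4 negative-specific and 5 positive-specific regions and did not pass. Of the 39 genes of MAPK output and receptor tyrosine kinases, KIT rose and EPHA4 fell, also when adjusted over the list alone.

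**Figure D3:**
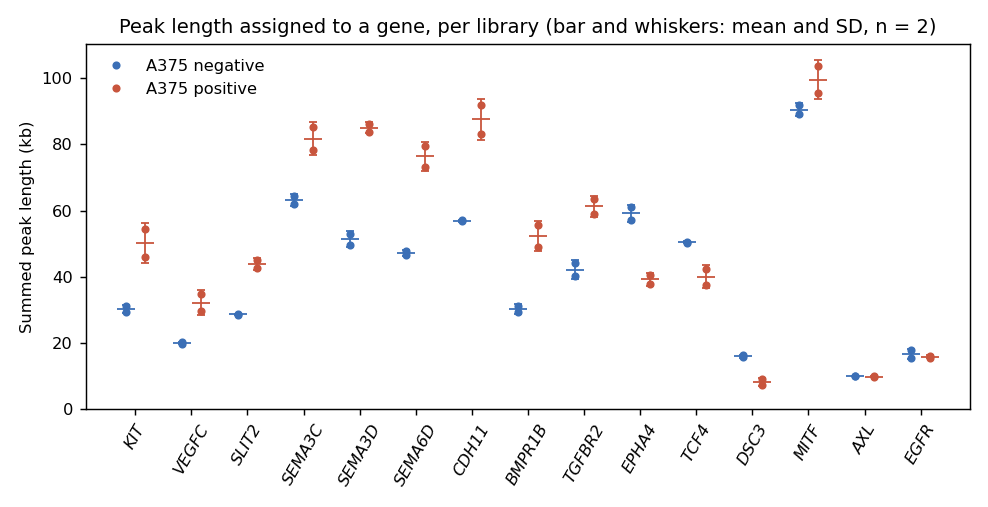
Summed H3K4me2 peak length in kb assigned to selected genes, with a point per library and the mean and SD of each line (n = 2). KIT, SEMA3D and SEMA6D lie higher in A375 positive, EPHA4 and DSC3 lower, and the points of EGFR overlap between the lines.

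In TGF-beta and BMP signalling, 5 of 31 genes rose (BMP2, BMPR1B, NOG, TGFBR2 and TGFBR3) and none fell, with INHBA added as a sixth when adjusted over the list alone. The type II TGF-beta receptor gene TGFBR2 had 4 positive-specific regions and 42.2 ± 2.74 against 61.3 ± 3.22 kb, and BMPR1B had 5 and 30.3 ± 1.43 against 52.3 ± 4.56 kb. Of these regions, the one ranked highest by peak width was intergenic and 320.2 kb from the start at TGFBR2. At BMPR1B it was intronic and 43.51 kb from the start. In the extracellular matrix list, 5 of 32 rose (COL5A2, LUM, POSTN, THBS2 and VCAN) and none fell. POSTN had no peak in A375 negative and only 3.285 ± 0.137 kb in A375 positive (SD, n = 2). In the other signalling and adhesion lists, 1 of 16 genes of epithelial-mesenchymal transition rose, the mesenchymal cadherin gene CDH11, which had 7 positive-specific regions and 56.9 ± 0.327 against 87.5 ± 6.23 kb. Its region ranked highest by peak width was intergenic, 831.4 kb from the start. CDH2 had 4 positive-specific regions and an adjusted p of 0.0671 (limma). ADAMTS9 and MMP16 rose and MMP13 fell among 32 proteases and inhibitors, CTGF, DLC1 and RBMS3 rose among 26 targets of YAP and TEAD, and DKK2 and SFRP2 rose among 39 genes of WNT signalling. These 5 lists gave the same counts when adjusted over the list alone. ITGA11 rose among 34 integrin and focal adhesion genes, but not when adjusted over the list alone.

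In the remaining lists at most 1 gene passed in a direction, apart from fibroblast markers. The cell cycle list had 1 call of 30, a fall at the kinase inhibitor gene CDKN1C, interferon and antigen presentation 1 of 28, a fall at OAS1, the histone modifiers 1 of 22, a rise at HDAC9, and NOTCH signalling 0 of 14, the same when adjusted over the list alone. Hypoxia and glycolysis had 1 rise of 21 (PDK1) and the homeobox and Polycomb-regulated genes 1 of 36 (HOXC8), and both were lost when adjusted over the list alone. HOXC8 had no peak in A375 negative and only 1.66 ± 0.209 kb in A375 positive (SD, n = 2). Of the markers of other cell types, FAP, LUM and PDPN rose among 11 fibroblast genes, with a fall at PDGFRB added when adjusted over the list alone. PDPN had no peak in A375 negative and only 2.84 ± 1.49 kb in A375 positive (SD, n = 2). KRT10 rose and the desmosomal gene DSC3 fell among 11 keratinocyte genes, CD3E fell among 10 immune genes and 0 of 10 endothelial genes passed. KRT10 had no peak in A375 negative and only 1.77 ± 0.152 kb in A375 positive (SD, n = 2). In the housekeeping list 1 of 22 rose, RAB7A. For these last 4 lists, the counts adjusted over the list alone were the same.

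As groups, none of the 24 lists passed as holding more or fewer genes with a specific region than random lists matched on the number of regions per gene. The power for shorter lists and for negative-specific regions was not simulated. All 48 adjusted p-values were 1, and 0 of 48 had an unadjusted p under 0.05. Axon guidance had 19 of 44 genes with a positive-specific region against 17.3 in random lists. The cell cycle list had 0 of 30 against a random mean of 2.77 with a central range of 0 to 6 (two-sided permutation p = 0.0866).

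Specific regions lay farther from genes' starts than shared regions, and so did regions called in other combinations of libraries. The promoter class took 7.87% of the shared regions, 2.78% of the negative-specific regions (37 of 1329, exact 95% interval 1.97% to 3.82%) and 1.35% of the positive-specific regions (50 of 3710, exact 95% interval 1.002% to 1.77%). Against shared regions the odds ratios were 0.335 (Fisher's exact test, two-sided, adjusted p = 2.05e-14) and 0.160 (adjusted p = 7.68e-68), and positive-specific against negative-specific regions gave 0.477 (adjusted p = 0.00124). The median distance to a start was 53.3 kb for negative-specific, 65.5 kb for positive-specific and 25.5 kb for shared regions. Specific regions were also narrower, with medians of 2492 and 2566 bp against 3913 bp for shared regions. A region counted as promoter class when any annotated region it overlapped was a promoter. Wider regions thus had more chances to count, and the promoter tests did not match regions on width. The 10101 regions called in other combinations, which follow no line, had 2.06% in the promoter class, a median distance of 45.6 kb and a median width of 2182 bp, so these traits were not particular to line-specific regions. Regions are not independent of each other, so these p-values describe the lists and not the spread between cultures.

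The chromosomes contributed unequally. Chromosome 4, with GABRA2, PCDH7, INTU, KIT and BMPR1B, had positive-specific calls at 10.6% of its 2926 regions against 6.36% of all regions (odds ratio 1.81, Fisher's exact test, adjusted p = 2.64e-17). Chromosomes 2, 5, 8 and 13 also had more (odds ratios 1.17 to 1.41), and chromosomes 11, 15, 16, 17, 19, 20 and 22 had fewer, with 0.307 at chromosome 19. Negative-specific regions were enriched on chromosomes 11 (odds ratio 1.86), 18 (1.82) and 20 (1.69) and depleted on chromosome 1 (0.606). Chromosome 11 thus went in opposite directions, with 111 negative-specific regions, an adjusted p of 1.38e-07 (exact), and 98 positive-specific regions, an adjusted p of 2.70e-10 (exact). With lists of equal length, chromosome 8 no longer passed (odds ratio 1.14, exact adjusted p = 0.254) and positive-specific regions were also enriched on chromosomes 1 and 21 and depleted on chromosome 14. Among wide peaks alone chromosome 4 was the single chromosome to pass, for positive-specific regions. Fisher's exact test takes regions as independent, whereas specific regions tended to lie side by side, so these p-values overstate the evidence. The tests also did not match regions on distance to a start, although specific regions lay farther from starts than shared ones. Only chromosome 11 was also compared within classes of distance, so for the others an effect of distance was not separated.

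**Figure D4:**
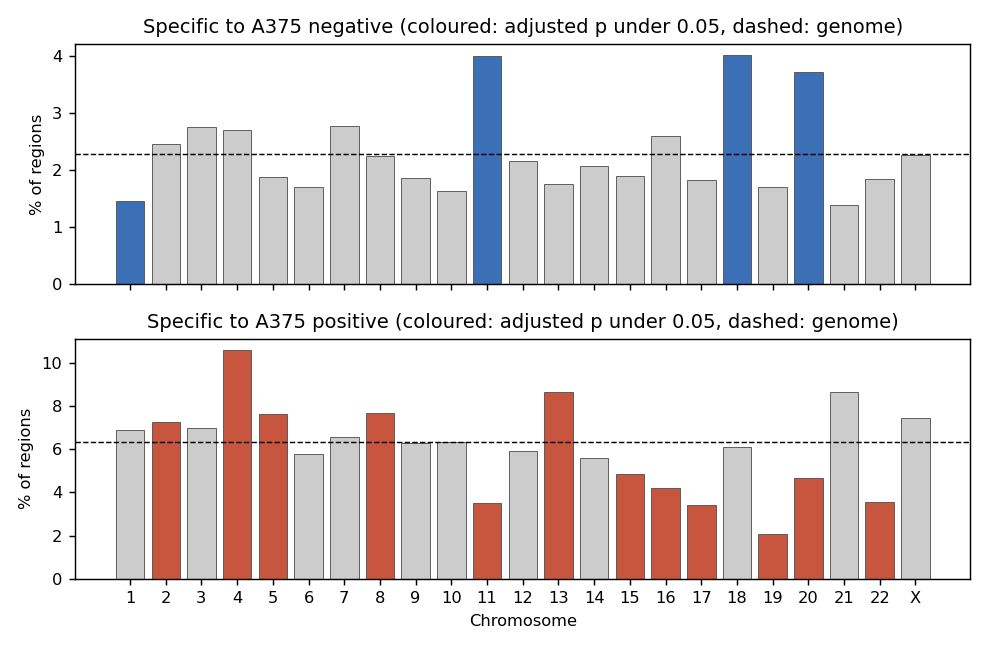
Percentage of the regions of each chromosome that were specific to A375 negative (top) or A375 positive (bottom), with the percentage over all regions as a dashed line. Coloured bars passed an adjusted p of 0.05 in Fisher's exact test, and chromosome 4 stands highest for A375 positive at 10.6%.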

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

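The authors' annotation covers far more regions than the H3K4me2 lists. Of its 140232 regions, 67130 (47.9%) overlapped no H3K4me2 peak of the 4 libraries, and they entered no comparison of the report. This stands out because it is signal in data outside the main measurement. The regions have a median width of 1911 bp over the whole table, and which sample each came from is not given in the sources used here, so no explanation was tested.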

How the results depend on the processing

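The use of peak width in place of scores, matching on distance and lists of equal length were chosen after the data were seen. More regions were positive-specific than negative-specific under every alternative run. Leaving out each library in turn gave 1660 to 2453 negative-specific and 4541 to 6319 positive-specific regions, since fewer libraries must then meet the definition. The deposited lists per line gave 2940 and 7327 because a peak in a single library is enough, peaks at or above the median width of their list 32 and 137, and lists of equal length 2162 and 2394, where equal length itself draws the counts together. A 50% overlap, a gap of 1 kb and autosomes alone stayed within 1.5 times the main counts. The Jaccard index within lines exceeded that between lines by 0.0653, and by 0.0567 for wide peaks. In the wide peaks 0 chromosomes passed for negative-specific and 1 for positive-specific regions, with fewer regions tested. The promoter odds ratios kept their direction and their side of the threshold, except that positive-specific against negative-specific gave no odds ratio among wide peaks, where no negative-specific region was at a promoter. No gene list passed under any alternative.

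No paired analysis was possible because the labels give no replicate numbers that pair libraries across the lines. For peak length, leaving out each library in turn gave 0 to 290 genes higher and 0 to 59 lower in A375 positive, with fewer libraries in the fit and a lone library assumed to vary like the others. Lists of equal length gave 729 lower, and the cause was not tested. Other added values, no filter and no centring stayed within 1.5 times, and a filter at 1 kb removed no tested gene. Of 28 named genes followed across these fits, all kept their direction in every fit that held them. Without centring, 2 of these genes were no longer called, KIT and TCF4. Other added values, filters and lists of equal length ended none, though SLC45A2 could not be fitted with equal lengths. Over all genes, 980 of the 1495 main calls were kept with lists of equal length and 1277 without centring. The other list members called were not followed one by one across these fits. Without an A375 negative library, 9 or 6 of the 18 called genes that could be fitted were no longer called, and without an A375 positive library all 19 of 19. Of 84 counts of specific regions at named genes with at least 2, 16 moved by over 1.5 times with the deposited lists per line and 31 with lists of equal length, 2 of them to 0. Leaving out a library moved 13 (positive replicate 1), 2 (positive replicate 2), 1 (negative replicate 1) and 6 (negative replicate 2). Alternatives resting on peak scores or read counts were not run, since the lists hold neither, and unknown depth limits any statement on regions without a peak.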

Other observations

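The tests of wide regions, of lists of equal length and the windows and runs themselves were chosen after the counts of specific regions were seen. The longest run of neighbouring positive-specific regions held 14 regions from 79152209 to 79820207 of chromosome 1, over IFI44, an interferon-induced gene, and ELTD1. The 2 Mb window around it, with PTGFR, had 19 positive-specific, 0 negative-specific and 20 shared regions of 43. A window from 78000001 to 80000000 of chromosome 7, at MAGI2-AS2, MAGI2-AS3 and GNAI1, had 18 of 38, and the next window, with SEMA3C and HGF, had 14 of 61. On chromosome 4, the window with GABRA2 had 16 of 35 and a window with the guanylate cyclase genes GUCY1A3 and GUCY1B3 and the growth factor gene PDGFC had 14 of 37. On chromosome 8, FAM110B lay in a window with 15 of 53.

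Among negative-specific regions, a window of chromosome 4 from 16000001 to 18000000, at MIR548AX, LDB2 and QDPR, had 15 of 59. Windows of chromosome 20 at LINC00494 and SULF2, and at TSHZ2 and ZFP64, had 13 of 63 and 12 of 67. The longest run held 5 regions, from 46679812 to 46917539 of chromosome 20. LINC00971 on chromosome 3 was nearest to 10 negative-specific and 3 positive-specific regions. On the same chromosome the window with CNTN6 had 10 negative-specific, 0 positive-specific and 10 shared regions of 31.

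More regions were positive-specific than negative-specific. If lower sensitivity in A375 negative were the whole cause, wide peaks should be about balanced. For wide peaks, at or above the median width of their lists, the ratio was 4.28 (137 to 32, exact 95% interval 2.90 to 6.50). Wide peaks were thus not balanced, and the excess was not confined to narrow ones. Width is not signal strength, however, and shared regions were also wider in A375 positive, with means of 4196 against 4101 bp. Wide peaks therefore cannot decide on sensitivity. For narrower regions lower sensitivity cannot be told apart from a difference between the lines either. There, lists of equal length gave a ratio of 1.11, and equal length forces the counts together. A difference between the lines remains a hypothesis, untested beyond these lists.

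Specific regions lay next to each other more often than chance within a chromosome and distance class. There were 551 neighbouring positive-specific pairs, against 340 in the highest of 1000 shuffles, so distance to a start did not account for them. The shuffles did not match the width or local spacing of regions. Sparse regions in gene-poor territory are therefore argued against only as far as distance to a start measures them. The negative-specific regions gave 167 against a highest of 55. A DNA copy number difference over megabases may contribute, because shared regions in windows with at least 5 positive-specific regions were wider in A375 positive than elsewhere, by 0.0339 on the log2 scale (95% bootstrap interval 0.0264 to 0.0409, permutation p = 0.0001, the smallest 10000 permutations can give). Regulation over a domain would widen them too, so this does not separate the hypotheses.

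Chromosome 11 had more negative-specific and fewer positive-specific regions. The distance of its regions from starts is argued against as the cause, since the odds ratio of negative-specific against positive-specific regions pooled over 5 distance classes was 3.34 (95% interval 2.51 to 4.42). That interval takes regions as independent of each other. A DNA copy number difference of chromosome 11 is a candidate explanation. Its shared regions had the lowest median log2 width ratio of A375 positive to A375 negative of the 23 chromosomes (rank 1), -0.0177 against a median of 0.0175 for the others. A shift of the whole chromosome would not by itself favour positive-specific regions locally, yet they outnumbered negative-specific ones 17 to 3 between 20 and 30 Mb and 16 to 3 between 100 and 110 Mb.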
